A study of Danio rerio with 12 samples.

How the data were processed

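Poly(A) RNA of microglia from zebrafish brains at 3 dpf was amplified by Smart-seq2 in 12 tubes of 3 picked cells, 3 tubes for each of siblings, mafba mutants, mafbb mutants and DMut. The deposited table holds raw counts per gene and tube, whole numbers that the authors made without normalization. Per the labels, reads were trimmed with Trim Galore and aligned with STAR to the build GRCz11, also called danRer11. Tool versions, the counting tool, the annotation release and the strand setting are not given in the sources used here. Genes are given by symbol and Ensembl ID, without positions, because no annotation of this build was used. The table has 35209 entries, 35117 Ensembl gene IDs and 92 ERCC spike-in sequences, of which 37 had a count. Of the gene IDs 27000 had a symbol, 8117 had none and 4682 shared their symbol with another ID. Many symbols are in the capitals used for human genes, and they stand for the zebrafish gene with the ID given.

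Total counts ranged from 10014888 to 17689266 and genes with at least 1 count from 5100 to 10521. The reads carried no molecular identifiers, so bounds from counts cover counting error only. A gene with 0 counts in a group was given a floor of 3 counts over the group, equal to 0.0801 CPM in siblings, 0.0678 in mafba, 0.0703 in mafbb and 0.0985 in DMut. Folds against such a group, written with at least, are bounds computed from the floor. They cover counting error only and are not lower limits on the change in RNA. Levels are given as mean CPM, on library sizes multiplied by the TMM factors, with the SD of 3 tubes, log2 fold changes with the SE of the model, and folds as ratios of mean CPM.

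Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, which left 9519 genes without the spike-ins. Libraries were scaled by TMM, 1 quasi-likelihood model with a term per genotype was fitted to all 12 tubes with robust=TRUE, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common dispersion was 4, a biological coefficient of variation of 2. The interaction contrast was DMut minus mafba minus mafbb plus siblings on the log2 scale. The lists were tested by camera with limma 3.58.1 and a preset correlation of 0.01, and beside it with an estimated correlation and by fry, a rotation test of the list by itself. p values were adjusted over the 22 lists with at least 5 tested genes. The lists were microglia, pan-myeloid, efferocytosis and complement C1q, lysosome, chemotaxis receptors, migration, MHC class II, inflammatory, interferon, neutrophil, neuronal, radial glia, erythroid, endothelial, epidermal and metaphocyte, cell cycle, immediate early and heat shock, mitochondrially encoded, cholesterol and lipid, glycolysis, oxidative phosphorylation, large Maf and ribosomal protein genes. The erythroid list had 4 tested genes and was not tested. Of 966 members written, 342 matched a symbol exactly, 343 but for case, 199 by the symbol shared by paralogues, 13 by a RefSeq name, 8 by a synonym, and 61 had no match. Library properties were compared by exact two-sided permutation tests over 10 splits.

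Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names mafba and mafbb, and the 10 higher and 10 lower called genes with the smallest p against siblings that have a gene name other than a clone name. Where fewer passed, all were named with up to 5 more per direction that did not pass. The rule allows 5 per direction in other contrasts and up to 4 members per list. Alternatives were DESeq2 size factors, TMMwsp, library size alone, no filter, a filter at CPM above 10 in 3 tubes, robust=FALSE, the replicate number as a block, limma voom with sample weights, DESeq2 1.42.0, the compared groups alone and each tube left out. Scaling to the spike-ins and leaving out mafba replicate 2 and mafbb replicate 3 were added after the data were seen. Genes tested stayed the same where tubes were left out, and DESeq2 used its own filter.

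The tests were checked on simulated data with 3 draws of 200 changed genes at the dispersion of the data. edgeR found 5.66% of genes raised 8-fold and 25.2% of those raised 64-fold, and 2.97% and 6.96% of those lowered as much. Of its calls 12.1% were false, above the 5% aimed at. DESeq2 found 38.1% of genes raised 64-fold with 87.2% of calls false, and limma voom 17.7% with 66.2% false. At a dispersion of 0.05 edgeR found 100% with 4.76% false. camera called a changed list in 3 of 3 draws and 0 of 60 random lists. Each gene was drawn independently, so these draws do not show how often camera calls lists of genes that move together. Whether the tubes of a genotype came from 1 dissociation or several is not given in the sources used here, so p values measure the spread between tubes and cannot part genotype from pool.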

Results

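RNA from microglia of 3-dpf (days post fertilisation) zebrafish brains was measured by Smart-seq2, a full-length cDNA amplification from poly(A) RNA, in 12 tubes. Each tube held 3 DsRed-positive cells picked by hand from brains of about 10 embryos of the Tg(mpeg1:DsRedx) line, in which the mpeg1 promoter marks macrophages and microglia. The groups were siblings, mafba mutants, mafbb mutants and fish labelled DMut, with 3 tubes in each. DMut is not spelled out in the sources and is read here as mutant in both genes. The title of the series sets the mutants against siblings, and the comparisons below ask which transcripts differed in each mutant group, what the loss of both genes added to the loss of either, and whether DMut departed from the sum of the single-mutant differences. Total counts were 12920090, 10726836 and 13085239 in sibling replicates 1 to 3, and 17689266, 12603769 and 15408465 in mafba replicates 1 to 3. They were 11072464, 12283921 and 16266247 in mafbb replicates 1 to 3, and 11580574, 10014888 and 11150969 in DMut replicates 1 to 3.

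Of the microglia list, 3 abundant genes held a smaller part of the RNA in DMut than in siblings. The 27 gene IDs of the microglia list took 5.66% ± 0.953 (SD, n = 3) of the gene counts in siblings, 3.52% ± 2.2 in mafba, 3.56% ± 1.17 in mafbb and 0.674% ± 0.253 in DMut. Its 3 most abundant members, apoeb, ccl34b.1 and apoc1, carried the difference, with 4.81% ± 1.11 in siblings and 0.00367% ± 0.00172 in DMut. The other members took 0.848% ± 0.171 (0.734% to 1.05%) in siblings and 0.67% ± 0.251 (0.456% to 0.947%) in DMut, which overlapped. Genes shared by myeloid cells took 1.91% ± 0.343 in siblings, 2.05% ± 0.262 in mafba, 2.23% ± 0.0925 in mafbb and 1.95% ± 0.386 in DMut. Neutrophil markers took 0.064% ± 0.0176 in siblings and 0.168% ± 0.043 in DMut, and epidermal and metaphocyte markers 0.00721% ± 0.00628 and 0.0941% ± 0.0683. Radial glia markers took 0.759% ± 0.294 in siblings and 0.0902% ± 0.00237 in DMut, most of it in siblings from the 1 gene GLUL, and the list was not called (adjusted p = 0.902). Erythroid markers, of which only 4 genes passed the count filter, took 0.0175% ± 0.0042 in siblings, 0.011% ± 0.00662 in mafba, 0.0173% ± 0.0118 in mafbb and 0.0109% ± 0.00551 in DMut. The mafbb tubes stood apart in the number of genes with at least 1 count, with 5756 ± 571 against 7428 ± 310 in siblings, 8571 ± 1779 in mafba and 8366 ± 812 in DMut. Spike-in RNA took 0.72% ± 0.0703 of all counts in mafbb and 0.265% ± 0.0742 in siblings. Cell cycle genes took 0.641% ± 0.671 in mafba, where replicate 2 alone reached 1.41% and 10521 genes, and 0.118% ± 0.0617 in siblings. For the microglia share in DMut, the gene number and the spike-in share in mafbb, every tube of the mutant group lay on 1 side of every sibling tube. The exact two-sided permutation test then gave p = 0.1, the smallest p that 3 tubes against 3 allow, and 0.326 after adjustment over 75 such comparisons.

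**Figure D1:**
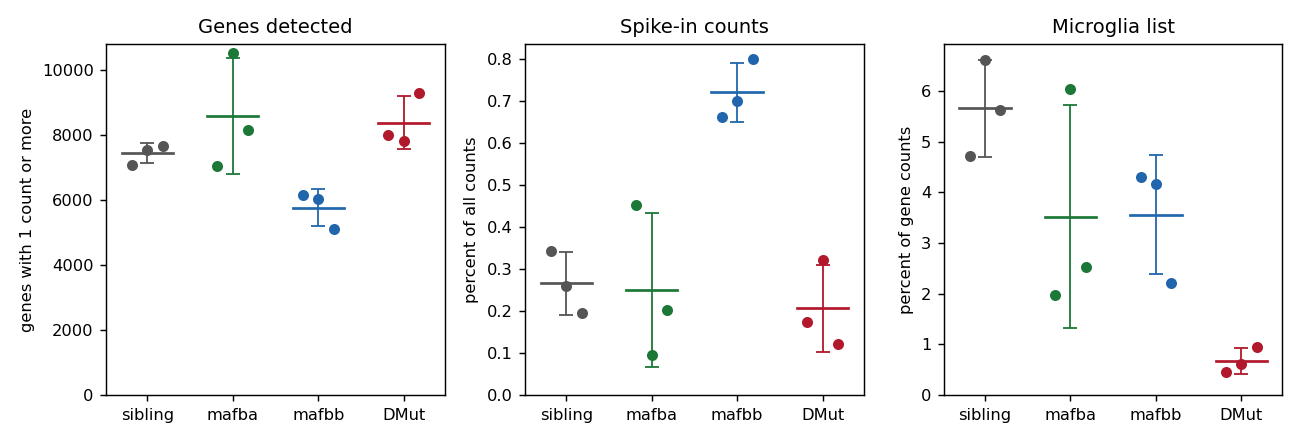
Genes with at least 1 count (left), spike-in counts in percent of all counts (middle) and counts of the microglia list in percent of gene counts (right) for the 3 tubes of each genotype. Points are tubes, lines are means and bars are SD; the mafbb tubes held 5100 to 6141 genes and the DMut tubes 0.46% to 0.952% microglia counts.

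Of the mutated genes, mafba did not pass the test over 9519 genes and mafbb was not tested. mafba (ENSDARG00000017121) was counted in all 12 tubes, at 248 ± 58.7 CPM (counts on the TMM effective library size, mean ± SD, n = 3) in siblings, 498 ± 114 in mafba, 225 ± 74.1 in mafbb and 572 ± 232 in DMut. Its log2 fold change against siblings was 1.21 ± 0.47 (SE) in DMut (adjusted p = 0.393), 1.01 ± 0.47 in mafba (adjusted p = 0.608) and -0.14 ± 0.47 in mafbb (adjusted p = 1). Every mafba tube (390, 487 and 618 CPM) and every DMut tube (346, 562 and 809 CPM) lay above every sibling tube (196, 311 and 236 CPM), where chance gives 10% for each pair of groups. The unadjusted p of edgeR was 0.0378 in mafba and 0.0141 in DMut. The sign in mafbb turned, to 0.32 with TMMwsp scaling and to 0.07 without sibling replicate 2 or mafbb replicate 3. mafbb (ENSDARG00000070542) had 5 counts in sibling replicate 3, 13 in mafba replicate 3, 17 in DMut replicate 3 and 0 in the other 9 tubes, so it was not tested. By counting error alone, a count of 0 over the 3 mafbb tubes allows up to 0.0703 CPM. Mutant transcripts can remain, so these counts check neither the mutations nor the labels.

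In DMut, 5 of the 21 tested members of the microglia list were lower than in siblings and 0 higher, while 13 had a log2 level ratio above -1. apoeb (ENSDARG00000040295), an apolipoprotein E gene and the most abundant member of the microglia list in siblings at 34545 ± 11140 CPM (n = 3), had no count in DMut, at least 350634-fold lower (adjusted p = 0.00753). Here and below such folds are computed from the floor of 3 counts and cover counting error only. Tubes of 1 genotype can differ widely, as with 1, 1 and 3567 counts of the gene penka in siblings. Such folds are therefore not lower limits on the change in RNA. ccl34b.1 (ENSDARG00000093608), a chemokine gene of microglia, fell from 9945 ± 3659 to 40.5 ± 22 CPM, a log2 fold change of -7.94 ± 0.69 (adjusted p = 0.00103). Of genes outside the microglia list, PSAP (ENSDARG00000013968), which encodes the precursor of the saposins, fell 5.35-fold from 10303 ± 2393 to 1926 ± 184 CPM (log2 -2.42 ± 0.23, adjusted p = 6.86e-10), and SLC37A2 (ENSDARG00000023394), a transporter known for the shrinkage of phagosomes in zebrafish microglia, fell 7.32-fold from 951 ± 162 to 130 ± 5.39 CPM (adjusted p = 1.96e-05).

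Of 9519 genes tested, 68 passed an adjusted p of 0.05, 24 higher and 44 lower in DMut (16 and 49 by library size, 22 and 25 by spike-ins). GADD45B (ENSDARG00000013576), a stress-induced gene, went from 298 ± 160 CPM in siblings to 0 counts, at least 3026-fold lower (adjusted p = 5.3e-12). A second ID with this symbol, ENSDARG00000027744, had 427 ± 48.5 CPM in siblings and 324 ± 112 in DMut. MTSS2 (ENSDARG00000087260) was at least 1935-fold lower (adjusted p = 4.68e-07) and the scavenger receptor gene stab1 (ENSDARG00000076484) at least 1011-fold lower (adjusted p = 0.000152), both with 0 counts in DMut. GPD1 (ENSDARG00000043701), a glycerol-3-phosphate dehydrogenase, had 564 ± 397 CPM in siblings and 1 count over the DMut tubes (adjusted p = 8e-07). ME3 (ENSDARG00000002305), a mitochondrial malic enzyme, had 182 ± 90.5 CPM in siblings and 1 count over the DMut tubes (adjusted p = 2.08e-05). The glutamate dehydrogenase gene glud1a (ENSDARG00000008816) fell 13.9-fold to 84.6 ± 33.2 CPM (log2 -3.79 ± 0.46, adjusted p = 4.47e-07). slc3a2a (ENSDARG00000036427), the heavy chain of amino acid transporters, fell 8.08-fold to 155 ± 32.3 CPM (log2 -3.01 ± 0.42, adjusted p = 9.11e-06), and SLC35F6 (ENSDARG00000016745) 8.76-fold to 134 ± 75.7 CPM (log2 -3.13 ± 0.47, adjusted p = 8.29e-05). These 8 with PSAP and SLC37A2 are the 10 lower genes with the smallest p, and all 10 stayed past the test when any tube of the 2 groups was left out. Other alternatives ended some of these calls. Spike-in scaling ended SLC37A2 (0.075) and SLC35F6 (0.0671), limma voom PSAP (0.657), slc3a2a (0.275) and SLC35F6 (0.296), and DESeq2 PSAP (0.632), glud1a (0.142), slc3a2a (0.375), SLC37A2 (0.407) and SLC35F6 (0.338).

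Among the higher genes, ATP6V0C (ENSDARG00000057853), a proton channel subunit of the V-ATPase, rose 3.32-fold from 1014 ± 162 to 3363 ± 1125 CPM (log2 1.73 ± 0.29, adjusted p = 0.000229). EPX (ENSDARG00000019521), a peroxidase gene, was at 0 in siblings and at 270 ± 123 CPM in DMut, at least 3366-fold higher (adjusted p = 0.0017). Whether this ID is the gene usually called mpx, a neutrophil marker, was not settled by the sources used here. The TNF receptor gene tnfrsf18 (ENSDARG00000076800) was at least 3470-fold higher at 278 ± 104 CPM (adjusted p = 0.00753). The acid phosphatase gene ACP5 (ENSDARG00000019763) rose 9.3-fold to 1160 ± 687 CPM (log2 3.22 ± 0.62, adjusted p = 0.00412). gsto2 (ENSDARG00000033285), a glutathione transferase, rose 3.58-fold (adjusted p = 0.004), the elongation factor gene eef1a1l1 (ENSDARG00000020850) 2.86-fold (adjusted p = 0.00753) and SCPEP1 (ENSDARG00000040072) 3.68-fold (adjusted p = 0.0123). MCM2 (ENSDARG00000102798), part of the helicase of DNA replication, went from 0.497 ± 0.86 to 209 ± 95.5 CPM (adjusted p = 0.00753). tnfaip2b (ENSDARG00000058160) was at least 2531-fold higher (adjusted p = 0.0129) and ppp2r2ab (ENSDARG00000006624), a phosphatase subunit, at least 636-fold higher (adjusted p = 0.0119). Of these 10, ATP6V0C passed without each tube in turn, but not with spike-in scaling (0.0523), limma voom (0.577) or DESeq2 (1). Spike-in scaling also ended gsto2 (0.279) and SCPEP1 (0.102), limma voom gsto2 (0.0806), eef1a1l1 (0.0692) and SCPEP1 (0.556), and DESeq2 gsto2 (1), ACP5 (0.396), eef1a1l1 (1) and SCPEP1 (1). robust=FALSE ended gsto2, ACP5, tnfrsf18, MCM2, SCPEP1, tnfaip2b and ppp2r2ab. The compared groups alone ended gsto2, MCM2, SCPEP1, tnfaip2b and ppp2r2ab. Leaving out mafba replicate 2 with mafbb replicate 3 ended SCPEP1, tnfaip2b and ppp2r2ab. DESeq2 size factors and library size alone ended SCPEP1, and the stricter filter tnfaip2b. EPX did not pass without DMut replicate 1 (adjusted p = 0.13), gsto2 without DMut replicate 2 (0.218), eef1a1l1 without sibling replicate 1 (0.0569) or MCM2 without DMut replicate 3 (0.0553). ACP5 did not pass without sibling replicate 2 (0.0579) or DMut replicate 2 (0.108), nor SCPEP1 (0.0622 and 0.139). tnfrsf18 was lost without sibling replicate 1 (0.0528), DMut replicate 1 (0.0634) or DMut replicate 2 (0.0696), ppp2r2ab without sibling replicate 1 (0.0528) or 2 (0.059), and tnfaip2b without DMut replicate 1 (0.435) or any sibling tube (0.0671, 0.0647 and 0.0612).

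**Figure D2:**
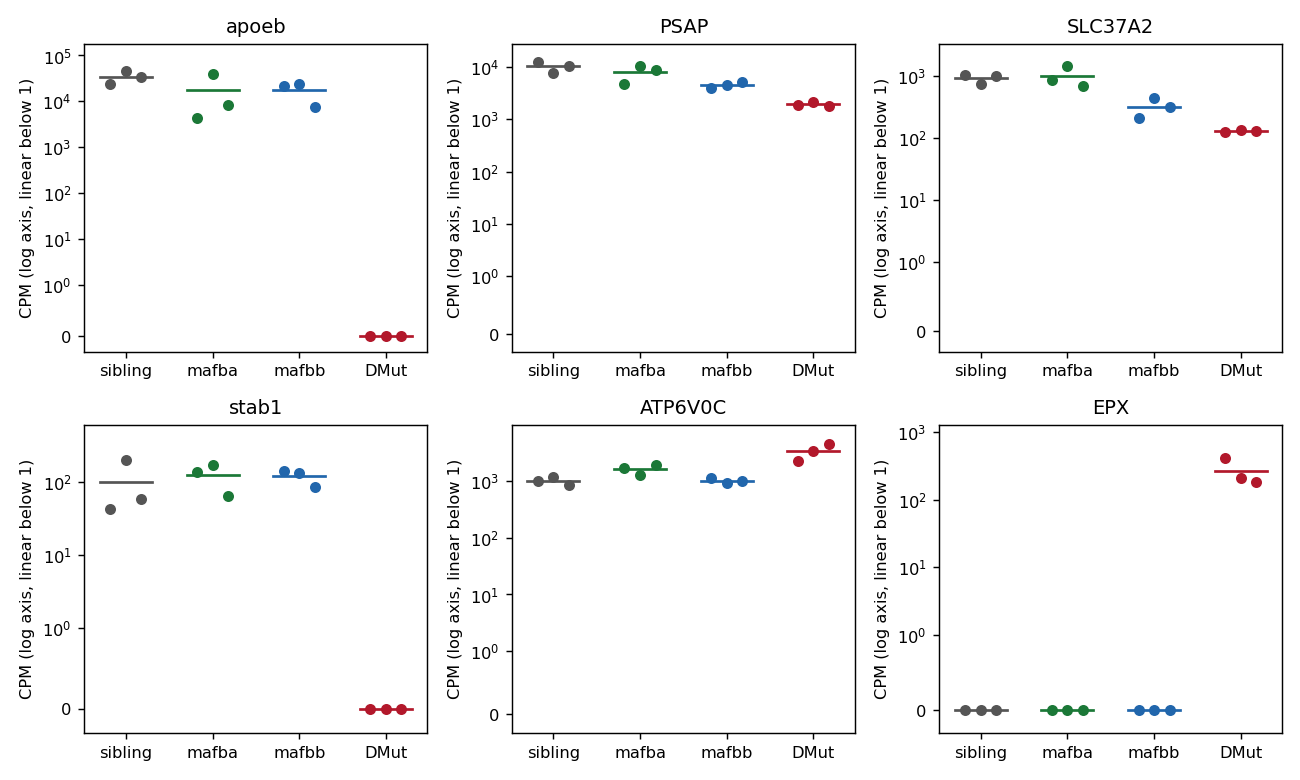
CPM of apoeb, PSAP, SLC37A2, stab1, ATP6V0C and EPX in the 3 tubes of each genotype, on a log axis that is linear below 1. Points are tubes and lines are means; apoeb and stab1 had 0 counts in the 3 DMut tubes, and EPX had 0 counts in the 9 tubes of the other groups.

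The microglia list fell in DMut as a group (camera adjusted p = 3.26e-05, and adjusted p = 0.0654 with an estimated correlation). Adjusted over the list alone 8 of its members were lower and 2 higher. Beside apoeb and ccl34b.1 the 5 lower over all genes were SLC7A7 (ENSDARG00000055226), an amino acid transporter subunit that microglia need to settle the zebrafish brain, with 1614 ± 303 against 326 ± 149 CPM (log2 -2.31 ± 0.39, adjusted p = 0.000392), apoc1 (ENSDARG00000092170), at least 40711-fold lower (adjusted p = 0.0159, and 0.0568 without sibling replicate 2), and lgals3bp.1, at least 14686-fold lower (adjusted p = 0.0215), named to complete the 5. limma voom ended the calls of apoeb (0.778), ccl34b.1 (0.978), SLC7A7 (0.433) and apoc1 (0.966), spike-in scaling those of SLC7A7 (0.378) and apoc1 (0.0618), and DESeq2 that of SLC7A7 (0.705). The replicate block ended that of apoc1. The list was not lowered throughout: 13 of the 21 members had a log2 level ratio above -1, among them the receptor genes csf1ra at 0.78 (adjusted p = 1) and csf1rb at -0.04 (adjusted p = 1), which were picked here after their values were seen. Members below -1 that did not pass were P2RY12, slco2b1 and havcr1. P2RY12 had 0 counts in DMut, a bound of -8.08 (adjusted p = 0.317). slco2b1 lay at -7.75 (adjusted p = 0.0856) and havcr1 at -1.29 (adjusted p = 0.0575). The efferocytosis and complement C1q list fell (adjusted p = 0.00195, and adjusted p = 0.0395 with an estimated correlation), with 3 of 20 members lower, SLC37A2, stab1 and SLC7A7, and 1 higher, the phosphatase gene PTPN6 (log2 1.69 ± 0.39, adjusted p = 0.0173). Adjusted over the list alone 7 were lower and 2 higher. Lists of other cell types moved in the same tubes, as given next.

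**Figure D3:**
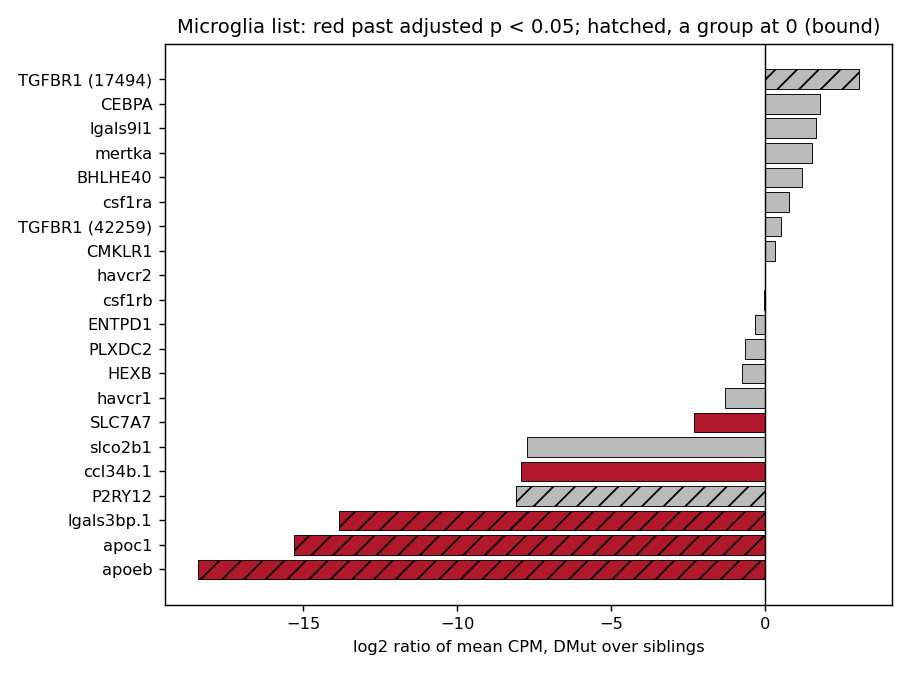
Log2 ratio of the mean CPM in DMut to that in siblings (n = 3 tubes each) for the 21 tested members of the microglia list. Red bars passed an adjusted p of 0.05, and hatched bars are bounds on counting error, from the floor of 3 counts, for genes with a group at 0 counts. csf1ra lay at 0.78, csf1rb at -0.04, slco2b1 at -7.75 and P2RY12 at a bound of -8.08.

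Markers of other cells did not move alike in DMut. The 5 tested epidermal and metaphocyte markers rose as a list (adjusted p = 0.000701, and adjusted p = 0.0395 with an estimated correlation), with all 5 above 0. None passed by edgeR, over all genes or adjusted over the list alone. cdh1, the E-cadherin gene, had 34.6, 35 and 26.7 CPM in DMut and 0.813, 0 and 0.233 in siblings (adjusted p = 0.673), and cd9b had 25.9, 17.6 and 20.8 CPM against 0 in the 3 sibling tubes (adjusted p = 0.393). The neutrophil list rose (adjusted p = 0.00743, and adjusted p = 0.106 with an estimated correlation), with 10 of 11 members above 0. No member passed over all genes and 1 higher member passed adjusted over the list alone, the protease gene mmp25b with 128, 144 and 197 CPM against 0 in siblings (adjusted p = 0.0582). Its member mpx found no gene of that name. EPX, called in DMut at 270 ± 123 CPM and 0 counts in siblings, was not counted in the list, so a neutrophil call among single genes stays open until its identity is known. The endothelial list fell (adjusted p = 0.00197, and adjusted p = 0.174 with an estimated correlation; 0.0948 by fry), with 8 of 8 members below 0 and 1 past the test, stab1, which the efferocytosis list also holds. pecam1a, FLI1 and TIE1 had 0 counts in DMut (adjusted p = 0.393 for each). Radial glia markers (adjusted p = 0.902, 8 members) and neuronal markers (adjusted p = 0.494, 9 members) were not called, with 0 members past the test by either adjustment. GLUL (ENSDARG00000099776), a glutamine synthetase gene of the radial glia list, had 5412, 3850 and 9451 CPM in siblings and 0, 58.7 and 0 in DMut (adjusted p = 0.393).

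The immediate early and heat shock list fell (adjusted p = 0.000879, and adjusted p = 0.0395 with an estimated correlation), with 5 of 51 members lower and 3 higher, and 6 and 3 adjusted over the list alone. The lower members included GADD45B, FOS (log2 -3.12 ± 0.61, adjusted p = 0.00269) and JUNB (ENSDARG00000074378, log2 -2.07 ± 0.46, adjusted p = 0.0119), and the higher members HSP90AA1 (log2 0.87 ± 0.20, adjusted p = 0.0147). Spike-in scaling and DESeq2 ended FOS (0.352 and 0.348), JUNB (0.399 and 0.878) and HSP90AA1 (0.399 and 1), and limma voom FOS (0.216) and HSP90AA1 (0.348). FOS did not pass without sibling replicate 1 (0.0528), JUNB without sibling replicates 1 (0.0569) or 3 (0.0612) or DMut replicate 3 (0.09), and HSP90AA1 without sibling replicates 2 (0.0625) or 3 (0.168) or DMut replicate 3 (0.0989). The list's share of counts went the other way, from 7.33% ± 0.553 in siblings to 9.17% ± 0.684 in DMut. Ribosomal protein genes rose as a list (adjusted p = 5.17e-09, and adjusted p = 0.471 with an estimated correlation), with 80 of 82 members above 0. RPL3 passed (adjusted p = 0.0455), though not with spike-in scaling (0.338), limma voom (0.476) or DESeq2 (1), nor without sibling replicates 1 (0.355), 2 (0.0642) or 3 (0.274) or DMut replicates 1 (0.0555) or 3 (0.365), and 5 members passed adjusted over the list alone. The cell cycle list rose (adjusted p = 1.67e-05, and adjusted p = 0.24 with an estimated correlation; 0.0948 by fry), with MCM2 past the test, 34 of 43 members above 0, and MCM2 and MCM3 past the test adjusted over the list alone. Cholesterol and lipid handling fell (adjusted p = 0.007, and adjusted p = 0.174 with an estimated correlation), with apoeb and apoc1 lower among 31 members and 3 lower adjusted over the list alone, PLIN2 included (log2 -3.13 ± 0.90, adjusted p = 0.11). Oxidative phosphorylation genes fell (adjusted p = 0.00955, and adjusted p = 0.637 with an estimated correlation; 0.314 by fry and 0.325 with spike-in scaling), with none of 75 past the test by either adjustment and atp5mc1 at log2 -1.16 ± 0.34 (adjusted p = 0.141).

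The other lists were not called in DMut. In the lysosome list (adjusted p = 0.942), of 59 members PSAP, NPC2 (log2 -2.33 ± 0.37, adjusted p = 0.00222) and TPP1 (log2 -1.64 ± 0.42, adjusted p = 0.0455) fell and ATP6V0C rose, with 5 lower and 3 higher adjusted over the list alone. NPC2 was not called with spike-in scaling (0.077), limma voom (0.664) or DESeq2 (0.703), nor TPP1 with spike-in scaling (0.404) or DESeq2 (1). TPP1 was lost without sibling replicates 1 (0.293), 2 (0.145) or 3 (0.0755) or DMut replicates 1 (0.227) or 3 (0.28). In the pan-myeloid list (adjusted p = 0.335, 34 members) the integrin gene itgae.1 fell (log2 -5.47 ± 1.22, adjusted p = 0.0157), PTPN6 rose, and so did LCP1, an actin-bundling protein gene (log2 1.03 ± 0.26, adjusted p = 0.04), with 5 lower and 6 higher adjusted over the list alone. Spike-in scaling and DESeq2 ended itgae.1 (0.0878 and 0.0648), PTPN6 (0.128 and 1) and LCP1 (0.399 and 1), and limma voom itgae.1 (0.0575) and PTPN6 (0.233). itgae.1 was lost without sibling replicate 3 (0.0768) or DMut replicate 3 (0.0576), PTPN6 without sibling replicates 1 (0.0894) or 2 (0.17) or DMut replicate 3 (0.185), and LCP1 without any of the 6 tubes (0.222, 0.206 and 0.0629 without siblings 1 to 3, and 0.114, 0.154 and 0.116 without DMut 1 to 3). In MHC class II (adjusted p = 0.902, 7 members) ifi30a, a lysosomal thiol reductase, fell (log2 -3.67 ± 0.66, adjusted p = 0.000685; 0.0523 with spike-in scaling and 0.205 by DESeq2), the single member past either adjustment. In the interferon list (adjusted p = 0.346, 18 members) gbp2 was at least 1208-fold lower (adjusted p = 0.0071), again the single member past either adjustment. In the inflammatory list (adjusted p = 0.111, and 0.0394 pointing up with spike-in scaling, 37 members) ccl34b.1 fell and tnfaip2b rose, with 2 lower and 3 higher adjusted over the list alone. In the list of migration genes (adjusted p = 0.633, 53 members) itgae.1 was the single call by either adjustment. No member passed by either adjustment among chemotaxis receptors (adjusted p = 0.649, 21 members), mitochondrially encoded transcripts (adjusted p = 0.633, 13 members), glycolysis genes (adjusted p = 0.902, 23 members) and large Maf and microglia transcription factors (adjusted p = 0.335, 31 members). The median log2 ratio was positive while the test pointed down for pan-myeloid (0.10), lysosome (0.35) and glycolysis (0.08) genes.

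In all 68 called genes the 3 DMut tubes did not overlap the 3 sibling tubes. Of all tested genes 17.2% did not overlap, where chance gives at most 10%, and 21 of the 68 had a group at 0. Chance gives less than 10% for genes with 0 counts in tubes of both groups, since such ties count as overlap. How much less was not computed, here or in the comparisons below. At an unadjusted p under 0.05 there were 1187 genes. limma voom called 423 genes, 38 of the 68 among them, and DESeq2 876, 24 of the 68 among them. Both turned the balance, with 275 higher and 148 lower by limma voom and 535 and 341 by DESeq2. Without sibling replicate 1 edgeR called 44.

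In mafba mutants no gene passed against siblings. edgeR called 0 of 9519 genes, with 744 at an unadjusted p under 0.05, while limma voom called 47 (32 higher, 15 lower) and DESeq2 583 (446 and 137). The smallest p values were those of ppp2r2ab, at 0 in siblings and 112 ± 17.4 CPM in mafba (adjusted p = 0.126), and of adgrg1 (ENSDARG00000027222), an adhesion receptor gene with 104 ± 44.1 CPM in siblings and 0 in mafba (adjusted p = 0.126). Neither passed. Among genes with higher values, MCM2 went from 0.497 ± 0.86 to 147 ± 95.4 CPM (adjusted p = 0.148), MCM3 from 0.113 ± 0.196 to 213 ± 140 (adjusted p = 0.376), tnfaip2b from 0 to 42.8 ± 65.2 (adjusted p = 0.408) and gsto2 from 376 ± 117 to 1024 ± 216 (adjusted p = 0.429). RASGEF1B had a log2 fold change of -1.41 ± 0.41, arl5c -1.60 ± 0.46, GADD45B (ENSDARG00000027744) -1.74 ± 0.52 and SAT1 -1.60 ± 0.48, each with an adjusted p of 0.608. 9.31% of tested genes did not overlap between the groups, where chance gives at most 10%. The count was 2 without sibling replicate 1, 1 without sibling replicate 3 and 2 without mafba replicate 2.

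The cell cycle list was the 1 list called in mafba, and the others had adjusted p of 0.0736 to 0.92. It rose (adjusted p = 1.41e-06, and adjusted p = 0.732 with an estimated correlation; 0.489 by fry), with 42 of 43 members above 0. None passed over all genes, and MCM2 and MCM3 passed adjusted over the list alone. mafba replicate 2 held the highest share of these transcripts, 1.41%. Neuronal markers passed, pointing up, without sibling replicate 2 (0.0462) or mafba replicate 1 (0.0116). Mitochondrially encoded transcripts did so without sibling replicate 2 (0.0453) or mafba replicate 2 (0.0263), and without mafba replicate 2 and mafbb replicate 3 together (0.0323). The microglia list was not called (adjusted p = 0.646), with none of 21 members past the test by either adjustment. Its member with the smallest p, lgals9l1, had a log2 fold change of 1.80 ± 0.57 (adjusted p = 0.608), and apoeb had 17764 ± 19823 CPM. Members passed adjusted over the list alone in 3 of the lists not called, 1 higher each: efferocytosis (adjusted p = 0.92), inflammatory genes (adjusted p = 0.356) and neutrophil markers (adjusted p = 0.356). The median and the test differed in sign for lysosome (median log2 0.10) and ribosomal protein genes (0.02), whose tests pointed down.

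In mafbb mutants 7 genes passed against siblings, 2 higher and 5 lower, and 4 of the 5 lower genes had no count in any mafbb tube. The balance depended on scaling, with 7 higher and 3 lower by TMMwsp and 2 and 68 by spike-ins. The 4 genes were SEPTIN8 (ENSDARG00000032606), a cytoskeletal GTPase gene with 135 ± 19.5 CPM in siblings, at least 1919-fold lower (adjusted p = 0.000312), si:ch211-288g17.3 (ENSDARG00000070959), at least 973-fold lower (adjusted p = 0.00098), ARPC1A (ENSDARG00000008383), a subunit of the actin-nucleating Arp2/3 complex, at least 1389-fold lower (adjusted p = 0.0261), and ARCN1 (ENSDARG00000002792), a coatomer subunit, at least 1715-fold lower (adjusted p = 0.0336). PSAP fell 2.26-fold to 4563 ± 591 CPM (log2 -1.18 ± 0.22, adjusted p = 0.0122). si:ch211-265g21.1 rose from 139 ± 60 to 673 ± 308 CPM (log2 2.27 ± 0.47, adjusted p = 0.027) and ppp2r2ab from 0 to 104 ± 144, at least 1294-fold higher (adjusted p = 0.0331). The mafbb tubes also detected fewer genes and held more spike-in counts than the sibling tubes, 5756 against 7428 genes and 0.72% against 0.265%. SEPTIN8 and si:ch211-288g17.3 passed without each tube in turn. si:ch211-265g21.1 was lost without sibling replicates 1 (0.11) or 3 (0.198) or mafbb replicates 1 (0.0689) or 2 (0.0761), and ARPC1A without sibling replicate 2 (0.116). PSAP was lost without sibling replicates 1 (0.112) or 3 (0.0888) or mafbb replicates 1 (0.102), 2 (0.0761) or 3 (0.0624). ppp2r2ab was lost without sibling replicates 1 (0.128), 2 (0.115) or 3 (0.113) or mafbb replicate 3 (0.154), and ARCN1 without any of the 6 tubes (0.112, 0.0954 and 0.105 without siblings 1 to 3, and 0.0578, 0.0519 and 0.0624 without mafbb 1 to 3). TMMwsp ended PSAP (0.265) and ARCN1 (0.0557), and DESeq2 did not call PSAP (1).

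Among genes that did not pass in mafbb, irf2a, PTPN11 and ubap2b had 0 counts in mafbb and an adjusted p of 0.0529 each, larp4ab 0.072 and asgr1c.1 0.0787. gstp1.2 (log2 1.63 ± 0.40, adjusted p = 0.0934), RPSA2 (log2 0.99 ± 0.28, adjusted p = 0.255), robo4, ID1 and tnfrsf18 (adjusted p = 0.263 each) had higher values. RPSA2 turned to -0.43 with spike-in scaling, and tnfrsf18 was counted in mafbb replicate 2 alone. Of all tested genes 1774 had an unadjusted p under 0.05 and 1101 of 9519 did not overlap between the groups, where chance gives at most 10%. limma voom called 216 genes (16 higher, 200 lower) and DESeq2 1665 (336 and 1329). edgeR called 4 genes without sibling replicate 1 or 3, 24 without mafbb replicate 1 or 2, and 15 without mafbb replicate 3.

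The lists called in mafbb all pointed up, and none was called with an estimated correlation. Ribosomal protein genes rose (adjusted p = 4.1e-10, and adjusted p = 0.542 with an estimated correlation), with 75 of 82 members above 0. Oxidative phosphorylation genes rose (adjusted p = 0.000147, and adjusted p = 0.542 with an estimated correlation), with 55 of 75 above 0. Mitochondrially encoded transcripts rose (adjusted p = 0.000194, and adjusted p = 0.542 with an estimated correlation), with 12 of 13 above 0. These 3 directions turned with spike-in scaling, which gave adjusted p of 0.682, 0.764 and 0.963 pointing down. Neuronal markers rose (adjusted p = 0.0346, and adjusted p = 0.542 with an estimated correlation), with 7 of 9 above 0, and the cell cycle list rose (adjusted p = 0.0206, and adjusted p = 0.612 with an estimated correlation), with 25 of 43 above 0. No member of these 5 lists passed by either adjustment. None of the 5 was called by fry, with adjusted p of 0.288 for ribosomal, 0.55 for oxidative phosphorylation, 0.245 for mitochondrially encoded, 0.33 for neuronal and 0.883 for cell cycle genes. Without mafbb replicate 3, oxidative phosphorylation (0.158) and cell cycle genes (0.0865) were not called. The neuronal list was not called without sibling replicates 1 (0.117) or 3 (0.141) or mafbb replicate 1 (0.266), nor the cell cycle list without sibling replicate 3 (0.218) or mafbb replicate 1 (0.533). The microglia list was not called (adjusted p = 0.746), with none of 21 members past the test and 1, the transcription factor gene CEBPA, lower adjusted over the list alone (log2 -2.79 ± 0.73, adjusted p = 0.263). Lysosome and glycolysis genes, not called here, pointed down and passed with spike-in scaling (0.00406 and 0.0157), and fry called glycolysis genes (0.0252). Median and test differed in sign for efferocytosis (median log2 -0.75), chemotaxis (-0.23), migration (-0.09), immediate early and heat shock (-0.10) and large Maf genes (-0.20), whose tests pointed up.

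The calls of DMut and mafbb shared 3 genes. si:ch211-265g21.1 and ppp2r2ab were higher in both, where independent lists would share 0.00504, and PSAP was lower in both, where 0.0231 would be shared. Independence does not hold, as both used the same siblings. In 20 simulated draws without any group difference, the 2 comparisons shared 0.2 calls on average, and mafbb had 0.95 calls on average and up to 5. In mafbb each of the 3 was lost without at least 4 of the 6 tubes, as given above. Across the 9519 genes the log2 fold changes of DMut and mafba had a correlation of 0.51, those of DMut and mafbb 0.46 and those of mafba and mafbb 0.48, where the shared siblings alone gave 0.50 in simulation. The covariances were 3.37, 3.46 and 2.98, where the shared siblings alone gave 2.64, 2.63 and 2.63. For the pairs with mafbb the 2 measures point apart. For DMut and mafba the correlation lay near the simulated value (SD 0.008) and the covariance above it (SD 0.059). A likeness of the mutants beyond their shared siblings stays open. Genes are not independent replicates, and the 3 sibling tubes were too few to be divided between the comparisons.

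Against mafba, DMut had lower levels of PSAP and SLC37A2 as it had against siblings. PSAP fell 4.18-fold (log2 -2.06 ± 0.23, adjusted p = 6.07e-08) and SLC37A2 7.87-fold (log2 -2.98 ± 0.42, adjusted p = 1.31e-05), from 8048 ± 2942 and 1022 ± 401 CPM in mafba (n = 3). GADD45B (ENSDARG00000013576) was at least 2804-fold lower (adjusted p = 6.32e-12), MTSS2 at least 1572-fold lower (adjusted p = 9.11e-07), and GPD1 went from 344 ± 224 CPM to 1 count over the DMut tubes (adjusted p = 1.91e-06). EPX was at least 3977-fold higher (adjusted p = 0.00207), tnfrsf18 at least 4100-fold higher (adjusted p = 0.00841) and adgrg1 at least 2078-fold higher (adjusted p = 0.00841), each from 0 counts in mafba. RASGEF1B rose 4.44-fold (log2 2.15 ± 0.41, adjusted p = 0.00456) and ACP5 7.47-fold (log2 2.90 ± 0.61, adjusted p = 0.0135). In all, 38 genes passed, 6 higher and 32 lower, and 30 of the 44 genes lower in DMut than in siblings were among them. limma voom did not call PSAP (0.723), RASGEF1B (0.41) or ACP5 (0.0833), nor DESeq2 PSAP (1), SLC37A2 (0.528), RASGEF1B (1) or ACP5 (0.712), and spike-in scaling ended RASGEF1B (0.202) and ACP5 (0.0624). The 5 higher genes depended on single tubes. EPX was lost without DMut replicate 1 (0.193), RASGEF1B without mafba replicates 1 (0.061) or 2 (0.0583), adgrg1 without mafba replicates 1 (0.0507) or 2 (0.0548) or DMut replicate 2 (0.121), and ACP5 without the same tubes (0.0731, 0.059 and 0.368). tnfrsf18 was lost without mafba replicates 1 (0.0887) or 2 (0.0548) or DMut replicates 1 (0.0827) or 2 (0.0892).

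The microglia list fell in DMut against mafba (adjusted p = 1.99e-09, and adjusted p = 0.0426 with an estimated correlation), with 6 of 21 members lower, and 9 lower and 1 higher adjusted over the list alone. havcr1, a phosphatidylserine receptor gene, was among them (log2 -1.98 ± 0.34, adjusted p = 0.000835). The efferocytosis list fell (adjusted p = 0.0028, and adjusted p = 0.056 with an estimated correlation), with 4 of 20 lower and 6 adjusted over the list alone. Cholesterol and lipid handling fell (adjusted p = 0.00341, and adjusted p = 0.112 with an estimated correlation), with 2 of 31 lower by either adjustment, apoeb and apoc1. The endothelial list fell (adjusted p = 0.00119, and adjusted p = 0.112 with an estimated correlation; 0.0544 by fry), with stab1 alone of 8 members lower by either adjustment. The epidermal list rose (adjusted p = 0.0028, and adjusted p = 0.056 with an estimated correlation), with none of 5 past the test by either adjustment. Ribosomal protein genes rose (adjusted p = 8.45e-12, and adjusted p = 0.406 with an estimated correlation; 0.0544 by fry), with 81 of 82 above 0 and none past the test by either adjustment. Pan-myeloid genes fell (adjusted p = 0.0204, and adjusted p = 0.357 with an estimated correlation; 0.0794 by fry), with itgae.1 alone of 34 past either adjustment. They were not called without mafba replicates 1 (0.135) or 3 (0.0896) or DMut replicate 2 (0.0601). Immediate early and heat shock genes fell (adjusted p = 0.0298, and adjusted p = 0.105 with an estimated correlation), with 2 of 51 lower, and 3 lower and 3 higher adjusted over the list alone. They were not called without mafba replicates 1 (0.135) or 3 (0.0896) or DMut replicates 2 (0.0956) or 3 (0.0502). Neutrophil markers rose (adjusted p = 0.0397, and adjusted p = 0.179 with an estimated correlation; 0.112 by fry), with none of 11 past the test by either adjustment. They were not called without mafba replicates 1 (0.0912) or 2 (0.114) or DMut replicates 1 (0.0701) or 2 (0.113). Median and test differed in sign for radial glia (median log2 0.22, test down), cell cycle (-0.52, up) and large Maf genes (-0.10, up). At an unadjusted p under 0.05 there were 764 genes. All 38 calls were free of overlap, as were 14.5% of tested genes, where chance gives at most 10%, and 16 had a group at 0. limma voom called 173 genes (96 higher, 77 lower) and DESeq2 503 (184 and 319), with 15 and 18 of the 38 among them, and edgeR 23 without mafba replicate 2.

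Against mafbb, the 5 lower genes with the smallest p in DMut were also lower in DMut than in siblings. GADD45B (ENSDARG00000013576) was at least 5038-fold lower (adjusted p = 1.71e-12), MTSS2 at least 1449-fold lower (adjusted p = 1.59e-06) and stab1 at least 1203-fold lower (adjusted p = 0.000217). GPD1 (206 ± 129 CPM in mafbb, n = 3, adjusted p = 5.19e-06) and ME3 (107 ± 21.9 CPM, adjusted p = 8.77e-05) had 1 count each over the DMut tubes. SEPTIN8 was at least 1761-fold higher (adjusted p = 8.77e-05) and MCM2 at least 2967-fold higher (adjusted p = 0.000242), both from 0 counts in mafbb. The mafbb tubes detected fewer genes than the DMut tubes, 5756 against 8366, and held more spike-in counts, 0.72% against 0.206%. Zeros in mafbb therefore do not part the mutation from lower detection. MCM2 was near 0 in siblings too, at 0.497 ± 0.86 CPM. ACP5 rose 18.9-fold (log2 4.24 ± 0.65, adjusted p = 0.000256), ATP6V0C 3.28-fold (log2 1.71 ± 0.29, adjusted p = 0.000369) and PDCD4 5.32-fold (log2 2.41 ± 0.45, adjusted p = 0.00156). DESeq2 called none of these last 3 (0.0762, 0.868 and 0.533), and limma voom neither ACP5 (0.0631) nor ATP6V0C (0.529). In all, 69 genes passed, 36 higher and 33 lower (24 and 59 by TMMwsp, 32 and 46 by library size, 345 and 21 by spike-ins), and 29 of the 44 genes lower in DMut than in siblings were among them. Of the 69 calls 37 had a group at 0 and 66 were free of overlap, as were 17.2% of tested genes, where chance gives at most 10%. At an unadjusted p under 0.05 there were 1957 genes. limma voom called 480 genes (441 higher, 39 lower) and DESeq2 1764 (1499 and 265), with 37 and 41 of the 69 among them.

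The microglia list fell in DMut against mafbb (adjusted p = 1.97e-06, and adjusted p = 0.0383 with an estimated correlation), with 5 of 21 members lower and 1 higher, CEBPA (log2 4.57 ± 0.79, adjusted p = 0.0128), and 8 lower and 2 higher adjusted over the list alone. The efferocytosis list fell (adjusted p = 0.00185, and adjusted p = 0.0383 with an estimated correlation; 0.0761 with spike-in scaling), with stab1 and havcr1 lower among 20, and 7 lower and 2 higher adjusted over the list alone. The epidermal list rose (adjusted p = 0.00185, and adjusted p = 0.0383 with an estimated correlation), with none of 5 past the test by either adjustment. Immediate early and heat shock genes fell (adjusted p = 0.000112, and adjusted p = 0.0331 with an estimated correlation; 0.127 by fry and 0.0761 with spike-in scaling), with 5 of 51 lower and 3 higher, and 6 and 5 adjusted over the list alone. The endothelial list fell (adjusted p = 0.00185, and adjusted p = 0.179 with an estimated correlation; 0.127 by fry), with stab1 alone of 8 past either adjustment. Oxidative phosphorylation genes fell (adjusted p = 3.53e-10, and adjusted p = 0.179 with an estimated correlation; 0.127 by fry and 0.534 with spike-in scaling), with 64 of 75 below 0 and none past the test by either adjustment. Mitochondrially encoded transcripts fell (adjusted p = 0.00389, and adjusted p = 0.372 with an estimated correlation; 0.385 by fry), with 10 of 13 below 0 and none past the test by either adjustment. That direction turned with spike-in scaling (adjusted p = 0.346), and the list was not called without DMut replicate 1 (0.0936). Pan-myeloid genes fell (adjusted p = 0.018, and adjusted p = 0.308 with an estimated correlation; 0.813 by fry and 0.679 with spike-in scaling), with itgae.1 lower and CORO1A higher among 34, and 2 lower and 4 higher adjusted over the list alone. They were not called without mafbb replicates 2 (0.0798) or 3 (0.0563). Cholesterol and lipid handling fell (adjusted p = 0.018, and adjusted p = 0.182 with an estimated correlation; 0.423 by fry), with 2 of 31 lower, apoeb and apoc1, and 3 lower and 1 higher adjusted over the list alone. It was not called without mafbb replicate 2 (0.0766) or DMut replicate 1 (0.0827). Radial glia markers fell (adjusted p = 0.0324, and adjusted p = 0.182 with an estimated correlation; 0.385 by fry and 0.0761 with spike-in scaling), with none of 8 past the test by either adjustment. They were not called without mafbb replicates 2 (0.0853) or 3 (0.11) or DMut replicate 1 (0.0883). Neutrophil markers were not called (adjusted p = 0.0581), with 10 of 11 members above 0 and a median log2 of 1.35. They were called pointing up by fry (0.00718), with the replicate block (0.0493), with spike-in scaling (0.0178), without the 2 tubes standing apart (0.019) and without mafbb replicate 3 (0.0197) or DMut replicate 3 (0.0497). Other lists not called here pointed up and passed with spike-in scaling, lysosome (0.00071), migration (0.0178), glycolysis (0.0226) and ribosomal protein genes (1.96e-07), and neuronal markers pointed down (0.0393). fry called lysosome (0.0429), glycolysis (0.00718), migration (0.0265) and large Maf genes (0.0265), pointing up. Median and test differed in sign for chemotaxis (median log2 0.42), migration (0.27) and interferon genes (0.42), whose tests pointed down.

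Between the single mutants 4 genes passed, all higher in mafba and at 0 in the 3 mafbb tubes, while TMMwsp gave 3 higher and 2 lower and spike-ins 264 and 0. The mafbb tubes also detected fewer genes than the mafba tubes, 5756 against 8571, and held more spike-in counts, 0.72% against 0.25%, so these zeros do not part the mutation from lower detection. The 4 genes were si:ch211-288g17.3, at least 3757-fold higher at 264 CPM (adjusted p = 0.000184), SEPTIN8, at least 1718-fold higher (adjusted p = 0.000184), MCM2, at least 2093-fold higher (adjusted p = 0.000891), and ARPC1A, at least 1184-fold higher (adjusted p = 0.0311). MCM2 was near 0 in siblings too, at 0.497 ± 0.86 CPM. ARCN1 (adjusted p = 0.0535) and PTPN11 (0.0699) did not pass. Nor did the genes with lower values in mafba: RASGEF1B (log2 -1.77 ± 0.41, adjusted p = 0.0797), adgrg1 (0.115), pmaip1 (log2 -1.61 ± 0.41, adjusted p = 0.12), arl5c (log2 -1.70 ± 0.46, adjusted p = 0.215) and BEND3 (0.25). RASGEF1B turned to 0.21 and arl5c to 0.37 with spike-in scaling. ARPC1A was lost without mafba replicates 2 (0.12) or 3 (0.101) and si:ch211-288g17.3 without mafba replicate 2 (0.186). ARPC1A was also lost with TMMwsp, library size alone, the stricter filter, mafba replicate 2 and mafbb replicate 3 both left out, and the compared groups alone. Its adjusted p there reached 0.398. SEPTIN8 was lost with the compared groups alone (0.0518). At an unadjusted p under 0.05 there were 1630 genes, and 12.3% of tested genes did not overlap, where chance gives at most 10%. limma voom called 239 genes (231 higher, 8 lower) and DESeq2 1571 (1444 and 127), each with all 4 among them. edgeR called 29, 23 and 17 genes without mafbb replicates 1, 2 and 3. Lists were not tested between the single mutants.

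DMut departed from the sum of the single-mutant differences in 20 genes, 8 above it and 12 below (4 and 20 by TMMwsp, 3 and 10 by DESeq2 size factors, 45 and 15 by spike-ins). Below the sum lay GADD45B (ENSDARG00000013576, adjusted p = 4.5e-11), MTSS2 (adjusted p = 3.08e-05), GPD1 (adjusted p = 8.83e-05), stab1 (adjusted p = 0.00141) and ME3 (adjusted p = 0.00271), which were counted in all 9 tubes of the other groups. They had 0 counts in DMut, or 1 count for GPD1 and ME3. Above it lay SEPTIN8 (adjusted p = 0.000585), adgrg1 (adjusted p = 0.0092), the proenkephalin gene penka (adjusted p = 0.0322), ACP5 (log2 3.93 ± 0.84, adjusted p = 0.0334) and ARPC1A (adjusted p = 0.0334). SEPTIN8 and ARPC1A were at 124 ± 129 and 68.2 ± 29.6 CPM in DMut, at 135 ± 19.5 and 97.7 ± 69.1 in siblings, and at 0 in mafbb. Neither was thus higher in DMut than in siblings. Their zeros do not part an interaction from the lower detection in the mafbb tubes. adgrg1 was at 141 ± 110 CPM in DMut and at 0 in mafba, and penka at 0 in both single mutants. penka was no higher in DMut than in siblings, with 76.8 ± 67.7 against 92.4 ± 160 CPM, and its counts were 1291, 1 and 1194 in DMut and 1, 1 and 3567 in sibling replicates 1 to 3. 9 of the 44 genes lower in DMut than in siblings and 1 of the 24 higher were among the 20. The microglia list lay below the sum (adjusted p = 1.41e-07, and adjusted p = 0.106 with an estimated correlation), with 3 of 21 members past the test, apoeb (adjusted p = 0.0334), ccl34b.1 (log2 -6.91 ± 0.79, adjusted p = 0.018) and havcr1 (log2 -2.15 ± 0.47, adjusted p = 0.0334), and 8 lower and 2 higher adjusted over the list alone. ACP5 was not called with TMMwsp (0.0682), DESeq2 size factors (0.0859), limma voom (0.349) or DESeq2 (0.475), nor ARPC1A with TMMwsp (0.0591) or DESeq2 size factors (0.0519). limma voom ended GPD1 (0.0679) and penka (0.138), and spike-in scaling ME3 (0.0784). ME3 was lost without sibling replicate 3 (0.0536) and adgrg1 without DMut replicate 2 (0.0885). ARPC1A was lost without sibling replicates 2 (0.204) or 3 (0.0549), any mafba tube (0.11, 0.239 and 0.243) or DMut replicates 1 (0.0596) or 3 (0.0772). ACP5 was lost without sibling replicates 1 (0.09) or 3 (0.0536), mafba replicate 1 (0.0847), any mafbb tube (0.141, 0.14 and 0.251) or DMut replicate 2 (0.228). penka was lost without sibling replicate 3 (0.352), any mafba tube (0.11, 0.0797 and 0.0827), any mafbb tube (0.136, 0.134 and 0.223) or DMut replicate 1 (0.0501). At an unadjusted p under 0.05 there were 1238 genes, limma voom called 41 genes (29 above the sum, 12 below) and DESeq2 1386 (957 and 429). edgeR called 12 without sibling replicate 3, 13 and 11 without mafba replicates 1 and 3, 39 and 35 without mafbb replicates 2 and 3, and 13 without DMut replicate 1. A test of any difference among the 4 genotypes called 80 genes, with 1136 at an unadjusted p under 0.05, while limma voom called 682 and the likelihood ratio test of DESeq2 0, with 965 at an unadjusted p under 0.05.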

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

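The tests of fewer counts in the mafbb tubes, of cells without myeloid transcripts, of 1 exchanged tube and of other myeloid cells were chosen after the result was seen, and the criterion of the detection test was extended after its value was seen.

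The interaction of the mutations differed from 0 in 20 genes. SEPTIN8 (adjusted p = 0.000585), adgrg1 (0.0092), penka (0.0322, not above its sibling level), ACP5 (0.0334) and ARPC1A (0.0334) were above the sum of the single-mutant differences. GADD45B (4.5e-11), MTSS2 (3.08e-05), GPD1 (8.83e-05), stab1 (0.00141) and ME3 (0.00271) were below it. SEPTIN8 and ARPC1A were at 0 in the mafbb tubes and, in DMut, not above their sibling level. Those zeros do not part an interaction from lower detection in mafbb. Of 100 drawn splits of the 12 tubes, the real one included, 2 gave as many genes, and the highest other gave 24. These splits mix all genotypes, so any difference between groups, such as that of DMut alone, could set the real one apart. They therefore cannot show that the interaction itself lies beyond chance.

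Below the sum lay 9 lists, none of them called with an estimated correlation. fry called 2 of the 9, microglia and efferocytosis, and spike-in scaling 3, microglia, endothelial and neuronal. With spike-in scaling the adjusted p was 0.353 for pan-myeloid, 0.148 for efferocytosis, 0.0515 for radial glia, 0.733 for immediate early, 0.733 for mitochondrially encoded and 0.793 for oxidative phosphorylation genes. By fry it was 0.218 for pan-myeloid, radial glia, endothelial and mitochondrially encoded, 0.226 for neuronal, 0.418 for immediate early and 0.393 for oxidative phosphorylation genes. Without the 2 tubes standing apart, neuronal, radial glia and oxidative phosphorylation genes were not called (0.066 each). They were microglia (adjusted p = 1.41e-07, and 0.106 with an estimated correlation), oxidative phosphorylation (0.000506 and 0.356), mitochondrially encoded (0.000567 and 0.293), pan-myeloid (0.00367 and 0.179) and endothelial genes (0.00627 and 0.178). The others were efferocytosis (0.0107 and 0.129), neuronal (0.0186 and 0.178), radial glia (0.0263 and 0.178) and immediate early and heat shock genes (0.0354 and 0.178). The efferocytosis list had 11 of 20 members above 0 although its test pointed down. The neuronal list was not called without mafba replicate 3 (0.0724) or mafbb replicate 1 (0.102), nor the radial glia list without mafba replicate 3 (0.0905) or mafbb replicates 2 (0.0572) or 3 (0.0662). The immediate early list was not called without sibling replicate 3 (0.0601), mafba replicates 1 (0.0791) or 3 (0.0793), mafbb replicates 2 (0.0509) or 3 (0.0662) or DMut replicate 2 (0.0974).

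Spike-in sequences, which no planned comparison used, took 0.72% of counts in mafbb and 0.265% in siblings. Groups of 3 tubes were too small for a test of single tubes.

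Of the 7 genes called in mafbb, 4 were at 0 in all 3 mafbb tubes. The mafbb totals were not lower than the sibling totals on average, 13207544 against 12244055, so thinning could hardly decide whether fewer counts were the cause. After thinning to equal totals the highest mafbb tube held 6073 genes and the lowest sibling tube 6955. Thinning does not address whether fewer molecules were captured. Genes counted in all sibling tubes and at 0 in all mafbb tubes numbered 437 against 201 expected from independent loss, a ratio of 2.18, below 3.78 in mafba and 6.24 in DMut, which met the criterion written beforehand for lower detection as the cause. Because the ratio falls as loss rises, the excess of 236 genes against 28.7 and 129 was added after the ratio was seen, and the 2 measures point apart. Lower detection and an effect of the mutation therefore cannot be told apart for these genes. The same limit holds for the 4 genes called between the single mutants, which were at 0 in the same 3 tubes. Of these, MCM2 was near 0 in siblings too, at 0.497 ± 0.86 CPM, so its 0 in mafbb was near the sibling level. SEPTIN8 and ARPC1A in the interaction share the limit, as do genes at 0 in mafbb that were called between DMut and mafbb.

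In DMut the microglia list took less of the counts than in any other group, because of apoeb, ccl34b.1 and apoc1. Its other members took 0.67% in DMut and 0.848% in siblings, with overlapping tubes. The values argue against microglia replaced by cells that lack the transcripts of the pan-myeloid list. Cells that are not myeloid but express genes of that list are not covered. With replacement by cells lacking these transcripts, the pan-myeloid share would have fallen with the microglia share, to 0.457% at most. The lowest DMut tube held 1.56%. That 13 of 21 microglia genes had a log2 level ratio above -1 was first taken to exclude fewer microglia as such, which it cannot do, since other macrophages express some of these genes. A single exchanged tube is excluded, since the lowest share of the 9 other tubes was 1.98% and the highest DMut share 0.952%. Other myeloid cells picked in place of microglia remain open, with a median log2 ratio of 0.10 in the pan-myeloid list, because microglia with an altered programme would keep these genes too. Nor was it settled whether EPX, at 270 CPM in DMut and 0 counts in the other groups, is the neutrophil gene usually called mpx. Of the 25 members written for the neutrophil list 20 matched a gene, and mpx was among those that did not. The mutation of both genes may also lower these transcripts, which was not tested apart from the genotype comparison.

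The cell cycle list rose in mafba, where replicate 2 held 1.41% of its counts in these genes. The call did not rest on that tube alone, since camera with the preset correlation still called the list without it (adjusted p = 0.00707). With that setting 6 of the 10 splits of these tubes, the real one included, called as many lists. A call of 1 list is thus not beyond chance here, and it cannot decide whether a dividing cell was picked. The list was not called with an estimated correlation (0.732), so its members were not shown to move beyond their joint spread.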

How the results depend on the processing

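Spike-in scaling and leaving out mafba replicate 2 with mafbb replicate 3 were chosen after the data were seen. A count was taken as changed beyond 1.5 times its value, and the cause was not tested for any change given here.

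With no filter the counts were 115 in DMut against siblings, 12 in mafba, 36 in mafbb, 77 in DMut against mafba, 134 in DMut against mafbb, 40 in mafba against mafbb, 61 in the interaction and 182 for any genotype difference. With the stricter filter they were 2 in mafbb and 47 for any difference. With robust=FALSE they were 36 in DMut, 3 in mafbb, 22 in DMut against mafba, 43 in DMut against mafbb, 12 in mafba against mafbb and 47 for any difference. DESeq2 size factors gave 13 in the interaction. With the replicate block they were 123, 11, 22, 76, 125, 26, 48 and 156 in the same order as without a filter, and neuronal genes in mafbb were not called (0.0648). The replicate numbers did not pair the tubes: the correlation of deviations between tubes of 1 number was -0.024 to 0.031.

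Spike-in scaling gave 3 in mafba, 70 in mafbb, 366 in DMut against mafbb, 264 in mafba against mafbb, 60 in the interaction and 255 for any difference. Without the 2 tubes standing apart there were 5 in mafba, 15 in mafbb and 17 in mafba against mafbb. limma voom gave 423, 47, 216, 173, 480, 239, 41 and 682, and DESeq2 876, 583, 1665, 503, 1764, 1571, 1386 and 0, in the order given for no filter. With only the compared groups in the fit there were 3 in mafba, 24 in mafbb and 13 in mafba against mafbb. Of genes lower in both DMut and mafbb, 2 were shared at an adjusted p under 0.1, PSAP and asgr1c.1.

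Leaving out each tube gave 44 to 57 genes in DMut against siblings, 0 to 2 in mafba, 4 to 24 in mafbb, 23 to 41 in DMut against mafba, 52 to 87 in DMut against mafbb, 3 to 29 in mafba against mafbb, 11 to 39 in the interaction and 55 to 86 for any difference.

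The log2 fold change of some genes that had not passed changed sign. With spike-in scaling RPSA2 in mafbb was -0.43, and RASGEF1B and arl5c in mafba against mafbb were 0.21 and 0.37. mafba in mafbb was 0.32 with TMMwsp, and 0.07 without the 2 tubes standing apart, without sibling replicate 2 or without mafbb replicate 3, with a range of -0.42 to 0.07 over the left-out tubes. tnfrsf18 in mafbb was 0.00 without mafbb replicate 2, with a range of 0.00 to 8.33. Lists changed direction too. With spike-in scaling mafbb pointed down for mitochondrially encoded (adjusted p = 0.963), oxidative phosphorylation (0.764) and ribosomal genes (0.682), and DMut against mafbb pointed up for migration (0.0178) and mitochondrially encoded genes (0.346). fry pointed up for migration genes in DMut against mafbb (0.0265).

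Spike-in scaling moved the median log2 fold change of all genes by 0.44 in DMut, 0.54 in mafba, -1.28 in mafbb, -0.12 in DMut against mafba, 1.70 in DMut against mafbb, 1.77 in mafba against mafbb and 1.12 in the interaction. TMMwsp moved it by 0.45 in mafbb, -0.44 in DMut against mafbb, -0.37 in mafba against mafbb and -0.48 in the interaction. Library size alone moved it by -0.13 in DMut, -0.23 in DMut against mafbb, -0.18 in mafba against mafbb and -0.13 in the interaction. In DMut against siblings the 68 calls were 24 higher and 44 lower, and 22 and 25 with spike-in scaling.

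Of the 73 named results past the test, DESeq2 size factors kept 67, TMMwsp 68, library size 66, no filter 73, the stricter filter 59, robust=FALSE 47, spike-in scaling 53, the 2 tubes left out 63, limma voom 48 and DESeq2 41 of the 71 it could test. The replicate block kept 72, losing apoc1 in DMut. The compared groups alone, not run for the interaction, kept 45 and lost 18. Losses of single genes by the stricter filter, robust=FALSE or the compared groups alone are not all named above. Of the 44 list calls, DESeq2 size factors kept 44, an estimated correlation 8, fry 17, spike-in scaling 28 and the 2 tubes left out 36. mafbb was counted in 3 tubes and not tested, and whether depth was the cause was not tested.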

Other observations

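The gene named first in this part was chosen after its values were seen, and the tests of other splits were planned.

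selenop (ENSDARG00000093549), a selenoprotein gene chosen after its values were seen, went from 2225 ± 184 CPM in siblings to 0 counts in DMut, at least 22579-fold lower (adjusted p = 0.00753).

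Splits of 3 tubes against 3 number 10 and are too few for a share under 0.05. The real split gave 68 genes in DMut against siblings and the highest other split 1. In mafba they gave 0 and 2, in mafbb 7 and 3, in DMut against mafba 38 and 0, in DMut against mafbb 69 and 2, and in mafba against mafbb 4 and 3. Called lists numbered 10 and 2 in DMut, 1 and 2 in mafba, and 5 and 3 in mafbb. For any genotype difference the real grouping gave 80 genes and the highest other of 100 splits 51. Only 1 of the 100, the real one, gave as many, which makes chance unlikely there but does not exclude it. The splits cannot part genotype from pool, and the likelihood ratio test of DESeq2 did not call any gene. In mafba 6 of the 10 splits called as many lists as the real one.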
